A study of Mus musculus with 12 samples.

How the data were processed

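Gene expression was measured by RNA sequencing of mouse hindlimb tissue in 12 libraries, 4 in each of 3 groups. Per the labels, the groups were lymphedema (LE), lymph node transfer (VLNT) and lymph node transfer with ABTAA (VtA). ABTAA is an antibody that binds angiopoietin-2, the product of Angpt2, and activates Tie2, the endothelial receptor encoded by Tek. Per the labels' protocols, whole tissue was flash frozen, RNA was extracted with Trizol, and libraries were made from polyadenylated RNA with a stranded TruSeq kit. Libraries are named here by group and replicate number, LE1 to VtA4. The labels do not say whether replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

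Per the submitters' processing notes, bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0 and StringTie 2.1.3b were used, and the builds GRCh38 and mm10 were named without a role. The strand setting used for counting, the gene annotation and the treatment of reads that map to several places are not given in the sources used here. The table deposited by the authors lists 45777 genes by NCBI gene ID and symbol. Per the file headers, it gives for each library a raw read count, whole numbers that sum to a different total in each library. It also holds FPKM, which the authors scaled by gene length and library total; these values were not used here. The TPM columns, also deposited by the authors and scaled to the same total in each library, served only for an alternative test. All 12 libraries matched a column by name. Of the gene IDs, 45679 were found in the RefSeq table of the mouse assembly GRCm38.p6, the assembly behind mm10, and coordinates are given on that assembly.

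The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM normalization and edgeR's default filter on low counts. The filter left 19740 genes, which held at least 99.87% of the counts of each library. All 12 libraries entered 1 fit of group means, so that the 3 groups shared 1 estimate of the spread, and 3 comparisons were taken from it. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Levels are CPM, counts scaled to equal TMM-adjusted library sizes. Log2 fold changes carry a standard error (SE) taken from the test statistic, and all group means are over n = 4 libraries unless another n is given. All tests were 2-sided.

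Before the data were examined, 42 gene lists were fixed. They cover blood and lymphatic endothelium, the Tie2 pathway, immune cells, signalling and metabolic groups, and the tissues that a piece of hindlimb can hold, such as muscle, skin, fat, tendon and nerve. A list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with adjustment over the 126 tests of 42 lists in 3 comparisons. Each list was also tested with a correlation estimated from the data, with fry, which asks whether its genes move one way on balance, and with an exact permutation test of its score, the mean log2 CPM of its genes per library. For 4 libraries against 4 the smallest exact p is 0.0286. Members of a list were also adjusted over the list alone.

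The rule for the genes named was also fixed before the data were examined. For each comparison it takes the 8 called genes with the largest rise and the 8 with the largest fall, if their mean level is at least 1 CPM and the 4 libraries of each group do not overlap. It adds 12 core genes of the angiopoietin pathway and of lymphatic endothelium, and up to 4 members of each list with the smallest p. Where fewer than 5 genes are called, it adds the 5 genes with the smallest p, given as values. Of the list members, the text names the first 2 of the 6 lists with the smallest camera p in each comparison. Genes named outside this rule are said to be so.

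The libraries held 56042030 to 72540147 counts. Shares of reads for single libraries carry 95% Wilson intervals; at this depth they are narrow, and they cover counting error only. Within groups, 18 pairs of libraries were compared: 0 were identical, and the smallest chi-square of a pair was 128 per degree of freedom, so each library was kept as its own sample. Genes with near-identical copies, such as Krt6a and Krt6b, pseudogenes, and genes that overlap another gene are uncertain, because the counting could split or mix their reads.

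The count test was tested on simulated data, drawn for the 19740 genes from the means, library sizes and dispersions of the libraries, with 50 genes changed at each fold size. For VLNT against LE, it recovered 0% of the genes changed 2-fold, 26% of those changed 4-fold, 78% of those changed 16-fold and 90% of those changed 64-fold. The shares for VtA against VLNT were 0%, 20%, 82% and 96%, and for VtA against LE 0%, 16%, 76% and 90%. The common dispersion of the libraries was 0.470, a biological coefficient of variation of 68.6%.

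The alternatives fixed before the data were examined were DESeq2 1.42.0, RLE and upper-quartile factors, TMM factors without the muscle, blood and epidermal lists, no filter and a stricter filter on low counts (at least 1 CPM in at least 4 libraries), and limma-voom with sample weights. They also included a fit of the 2 compared groups alone, the replicate number as a block, the skeletal muscle list or the keratinocyte list as a covariate, limma on log2(TPM + 1) and log2(TPM + 0.1), a 2-fold minimum, and each library left out in turn. After the data were seen, fits without LE4 and VtA1, without LE1, LE4 and VtA1, with both covariates, and with library size alone were added. The 2 comparisons against LE share the LE libraries, so 20 sets of unchanged groups were simulated with shared controls, and the LE libraries were also split 2 and 2.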

Results

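The transcriptome of mouse hindlimb tissue was profiled in lymphedema (LE, n = 4), after lymph node transfer (VLNT, n = 4) and after lymph node transfer with the Tie2-activating antibody ABTAA (VtA, n = 4). Library totals were 63.4 ± 6.93 M counts in LE (SD), 67.4 ± 7.04 M in VLNT and 67.7 ± 7.67 M in VtA, with a range of 56.04 to 72.54 M.

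The pieces of tissue differed in what they held. Keratinocyte genes took 3.08% ± 2.12 of the reads in LE (SD, n = 4), 2.79% ± 1.12 in VLNT and 0.555% ± 0.575 in VtA. In LE4 and VtA1 the share was only 0.00279% (95% Wilson interval 0.00267 to 0.00292) and 0.00449% (0.00432 to 0.00467), against 3.52% to 4.85% in LE1 to LE3. Skeletal muscle genes took 12.1% ± 11.8 in LE, 15.3% ± 6.66 in VLNT and 24.3% ± 2.69 in VtA, from 1.94% in LE2 (1.94 to 1.95) to 28.7% in LE4 (28.7 to 28.8). Mitochondrially encoded transcripts took 9.24% ± 8.05, 12.8% ± 1.48 and 18.6% ± 5.17 of the reads in the 3 groups. LE1 stood apart in having 0.433% mitochondrial reads (0.431 to 0.435) and 17.9% of reads in ribosomal protein genes. A principal component that held 58.1% of the variance placed LE4 (237) and VtA1 (220) at one end and LE2 (-156) and LE1 (-134) at the other. The component with 18.2% separated LE1 (218) from the other libraries (-57.4 to 55.0).

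**Figure D1:**
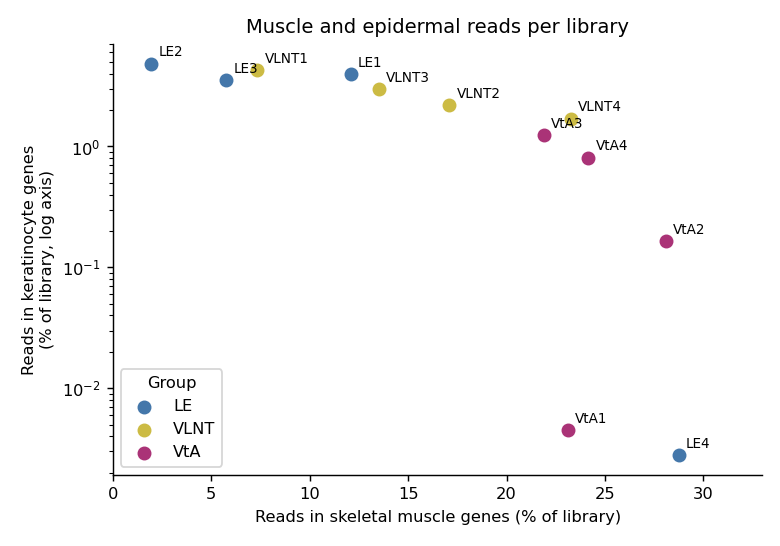
Share of reads in the fixed skeletal muscle genes (x axis, % of library) against the share in the fixed keratinocyte genes (y axis, % of library, log axis), 1 point per library, coloured by group. LE4 and VtA1 have 0.00279% and 0.00449% keratinocyte reads, and the 4 VtA libraries lie between 21.9% and 28.1% muscle reads.

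The comparison of VLNT with LE addressed what the transfer adds to lymphedema. Interferon response genes were lower in VLNT, and cell cycle genes were higher only while LE4 was in the fit. Of 28 interferon genes, 23 were lower (median log2 fold change -0.44) and the list fell by camera (adjusted p = 0.00216; adjusted p = 0.788 with an estimated correlation). Of 27 cell cycle genes, 22 were higher (median 0.26) and the list rose (adjusted p = 0.00567; adjusted p = 0.851 with an estimated correlation). Without LE4, which scored -0.84 against 3.81 to 4.07 in LE1 to LE3, the cell cycle difference turned from 0.80 to -0.20 relative to all genes (adjusted p = 0.364), and without VLNT1 it lost its call (0.69, adjusted p = 0.109). The interferon call was lost without LE3 (-0.21, adjusted p = 0.565) and without VLNT2 (-0.28, adjusted p = 0.0696). From -0.42 in the fit of all libraries, the difference moved to -0.78 without LE4 (adjusted p = 2.26e-06) and -0.68 without VLNT1 (adjusted p = 9.55e-06). Without LE1 it was -0.23 (adjusted p = 0.00792), and these 3 fits kept the call. Igtp, an interferon-inducible GTPase, stood at 11.1 ± 2.12 CPM in VLNT and 19.0 ± 4.78 in LE (log2 fold change -0.78 ± 0.26 SE, n = 4). Bst2, an antiviral membrane protein, was at 15.7 ± 8.98 and 55.5 ± 78.5 (-1.82 ± 0.81). Mcm2, a part of the replicative helicase, was at 18.9 ± 3.20 CPM in VLNT and 13.7 ± 2.096 in LE (0.47 ± 0.22). Ccne2, a cyclin of the start of DNA synthesis, was at 5.06 ± 0.274 and 2.70 ± 1.46 (0.91 ± 0.49).

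Of 6 further lists called in this comparison, 5 rose. Of 13 mitochondrially encoded genes 12 were higher (median 0.20, adjusted p = 0.00771), and of 22 keratinocyte genes 13 (median 0.32, mean 0.04, adjusted p = 0.0108). Of 11 slow muscle fibre genes 6 were higher (median 0.22, adjusted p = 0.0368) and of 14 sebaceous gland genes 12 (median 0.59, adjusted p = 0.0377). The skeletal muscle list was called higher (adjusted p = 0.0137) although 13 of its 26 genes were lower and its mean log2 fold change was -0.05, with a median of 0.01. Lymph node stroma chemokines were lower in 9 of 11 genes (median -0.62, adjusted p = 0.0453). With an estimated correlation none of these 6 passed (adjusted p = 0.788 with an estimated correlation for mitochondrial, slow muscle, sebaceous and chemokine genes, and 0.879 for keratinocyte and skeletal muscle genes). None of the 8 lists kept its call with each single library left out. Without LE1, which had 0.433% mitochondrial reads, the mitochondrial difference fell from 1.30 to 0.021 relative to all genes and the test pointed down (adjusted p = 0.940). Without LE4, keratinocyte genes turned from 1.97 to -0.30 (adjusted p = 0.374) and sebaceous gland genes moved to 0.024 (adjusted p = 0.991). Without LE2, skeletal muscle genes turned to -0.091 (adjusted p = 0.677) and slow fibres lost their call (0.38, adjusted p = 0.606). Without LE1, chemokines stood at 0.013 (adjusted p = 0.415), from -0.47 with all libraries. They moved the other way without LE4 (-1.18, adjusted p = 0.00159) and without VLNT1 (-0.82, adjusted p = 0.00858). The spread within LE was wide: Lgals7, a keratinocyte galectin, was at 847 ± 589 CPM in VLNT and 2187 ± 3092 in LE (-1.37 ± 1.70 SE, n = 4). Sfn, stratifin, was at 479 ± 188 and 1006 ± 1365 (-1.07 ± 1.43). Tcap, a sarcomere protein, was at 707 ± 347 and 1686 ± 1813 CPM (-1.26 ± 1.00), and Tnni2, the fast troponin I, at 3712 ± 1500 and 8483 ± 9186 (-1.19 ± 1.02). Atp2a2, the calcium pump of slow muscle, was at 248 ± 107 and 116 ± 55.8 (1.09 ± 0.54), and Myh7, the slow myosin, at 153 ± 157 and 34.2 ± 60.8 (2.16 ± 1.39). The mitochondrial genes ND5 (8535 ± 3353 against 5367 ± 6692 CPM) and ND4L (1499 ± 574 against 960 ± 1155) had log2 fold changes of 0.67 ± 1.09 and 0.64 ± 1.06.

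No single gene passed in VLNT against LE: edgeR called 0 of 19740 genes, with 396 at an unadjusted p under 0.05 where evenly spread p-values give 987. With these 8 libraries grouped 4 and 4 in every other way, the median was 832.5 such genes (highest 5861). DESeq2 called 1 gene, Gm9247, a pseudogene at 18.3 ± 28.1 CPM in LE (59.5 in LE1) and 0.130 ± 0.0491 in VLNT. Limma-voom with sample weights called 1362 (1251 higher, 111 lower). The 5 genes with the smallest p had adjusted p = 0.99992 by edgeR. They included Has3, a hyaluronan synthase (chromosome 8, 106870242 to 106882902), at 23.1 ± 15.1 CPM in VLNT and 5.28 ± 1.80 in LE (2.13 ± 0.47 SE, n = 4), and Gm9247 (-7.11 ± 1.71). Tgtp1, an interferon-inducible GTPase, was at 5.38 ± 1.66 and 12.7 ± 3.27 CPM (-1.24 ± 0.31). The long non-coding RNA LOC115490193 was at 0.134 ± 0.0560 and 0.0106 ± 0.0211 CPM, and Pde9a, a phosphodiesterase, at 1.47 ± 0.334 and 3.803 ± 1.74 CPM (-1.37 ± 0.40). No member of a list passed when adjusted over the list alone. Without LE4, 17 lists were called (6 higher, 11 lower) in place of 8 (6 higher, 2 lower), 5 of them shared. Without VLNT2, 5 lists were called.

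The comparison of VtA with VLNT addressed what the antibody adds to the transfer. Genes of cell division, inflammation and skin were lower in VtA, and genes of muscle and oxidative metabolism higher. The cell cycle list was lower in 26 of 27 genes (median -1.90, adjusted p = 6.96e-08 by camera) and inflammatory cytokines in 21 of 22 (median -2.55, adjusted p = 7.91e-07). Macrophage and monocyte genes were lower in 23 of 23 (median -1.44, adjusted p = 5.29e-06). Oxidative phosphorylation genes encoded in the nucleus were higher in 28 of 28 (median 0.74, adjusted p = 7.91e-07). Each of these 4 calls was lost with an estimated correlation (adjusted p = 0.788 with an estimated correlation).

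Mcm5, a helicase part, was at 3.74 ± 1.95 CPM in VtA and 17.7 ± 6.83 in VLNT (log2 fold change -2.24 ± 0.73 SE, n = 4). Plk1, a mitotic kinase, was at 1.79 ± 1.21 and 9.31 ± 3.08 (-2.37 ± 0.79). The chemokine gene Ccl3 was at 0.0889 ± 0.0706 CPM in VtA and 15.5 ± 20.4 in VLNT. Cxcl5, a neutrophil chemokine, was at 0 counts in each VtA library, which allows up to 0.0755 CPM in VtA1, and at 7.72 ± 5.82 CPM in VLNT. VLNT4 held only 4 counts of it, against 480 to 1001 in VLNT1 to VLNT3. Cd14, a receptor of monocytes, was at 2.80 ± 1.13 and 39.9 ± 45.02 CPM (-3.83 ± 1.42). Cd68 was at 10.6 ± 6.99 and 35.4 ± 15.1 (-1.74 ± 0.65). Cox5a and Uqcrfs1, subunits of the respiratory chain, were at 333 ± 97.1 and 366 ± 91.7 CPM in VtA against 171 ± 45.4 and 197 ± 56.1 in VLNT (0.96 ± 0.64 and 0.89 ± 0.60). None of these genes passed on its own (adjusted p = 0.653, edgeR).

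Tissue markers moved with these groups. Keratinocyte genes were lower in 22 of 22 (median -1.64, adjusted p = 3.98e-05), hair follicle genes in 19 of 19 (median -5.32, adjusted p = 0.00343) and sebaceous gland genes in 13 of 14 (median -1.71, adjusted p = 0.00455). Skeletal muscle genes were higher in 26 of 26 (median 1.11, adjusted p = 1.77e-05) and tendon genes in 10 of 10 (median 1.28, adjusted p = 0.00135). All 5 calls were lost with an estimated correlation (adjusted p = 0.788 with an estimated correlation). Among VLNT libraries, the hair follicle score was high only in VLNT1 (5.86) and VLNT2 (3.16). VLNT3 (-2.43) scored below VtA3 (0.12) and VtA4 (-2.24), and so did VLNT4. The hair follicle difference relative to all genes fell from -3.11 to -1.47 without VLNT1, and the call was lost (adjusted p = 0.114 by camera). Flg, the filaggrin gene of cornified skin, was at 52.3 ± 47.1 CPM in VtA and 1237 ± 193 in VLNT (-4.56 ± 1.58 SE, n = 4). Krt1 was at 420 ± 462 and 3428 ± 1076 (-3.03 ± 1.55). Tcap was at 1719 ± 329 and 707 ± 347 CPM (1.28 ± 1.00). Casq1, the calcium store protein of fast fibres, was at 3564 ± 741 and 1532 ± 839 (1.22 ± 0.96). The share of keratinocyte reads was 0.555% ± 0.575 in VtA and 2.79% ± 1.12 in VLNT, and no VtA library reached the lowest VLNT library (1.24% against 1.70%).

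Further immune and matrix lists fell in VtA against VLNT, again beside the lower skin and higher muscle shares. They were T cells (23 of 25 lower, median -1.57, adjusted p = 5.30e-05), fibrosis and extracellular matrix (24 of 28, median -1.44, adjusted p = 0.000271), matrix proteases (17 of 19, median -1.80, adjusted p = 0.000346) and immediate early genes (18 of 20, median -0.98, adjusted p = 0.00188). Complement (18 of 19, median -0.72, adjusted p = 0.00713), Th2 genes (11 of 14, median -0.88, adjusted p = 0.0108), neutrophils (10 of 16, median -1.36, adjusted p = 0.0108) and mast cells (12 of 13, median -1.38, adjusted p = 0.0109) were lower too. Dendritic cells (16 of 17, median -0.85, adjusted p = 0.0209), Th1 and cytotoxic genes (11 of 14, median -1.02, adjusted p = 0.0244) and interferon response (25 of 28, median -0.64, adjusted p = 0.0260) fell. Plasma cells (12 of 13, median -1.35, adjusted p = 0.0273) and lymph node stroma chemokines (10 of 11, median -1.48, adjusted p = 0.0395) also fell. Blood endothelial genes rose in 21 of 25 (median 0.40, adjusted p = 0.00771), as did muscle regeneration genes (13 of 15, median 0.74, adjusted p = 0.0178). Mitochondrially encoded genes (13 of 13, median 1.06, adjusted p = 0.0244) and endothelial targets of Foxo1 (14 of 17, median 0.27, adjusted p = 0.0447) rose as well. With an estimated correlation none passed (adjusted p = 0.788 with an estimated correlation, but 0.879 for interferon and 0.851 for mitochondrial genes). With epidermis content as a covariate, Th1 genes (0.17), interferon response (0.038) and dendritic cells (0.079) turned higher relative to all genes, and mitochondrial genes turned lower (-0.048). With muscle content, interferon response (0.013) and hair follicle genes (0.067) turned higher. Of the 26 lists, 13 kept their call with each single library left out: cell cycle, cytokines, macrophages, T cells, Th2, fibrosis, proteases, immediate early, keratinocyte, sebaceous, skeletal muscle, tendon and oxidative phosphorylation genes. Without VLNT1, 8 lists lost their call, among them plasma cells, whose score was 3.97 in VLNT1 and 0.94 to 1.30 in the other VLNT libraries. The plasma cell difference then fell from -0.99 to -0.28 relative to all genes (adjusted p = 0.348). The interferon response difference fell from -0.34 to -0.072 (adjusted p = 0.460), with a score of 3.81 in VLNT1 and 2.64 to 2.76 in the other VLNT libraries. It also lost its call without VtA1 and without VtA4. Without VtA1, 7 lists lost their call, and without VtA4, 7. Without VtA1 keratinocyte genes moved from -3.24 to -1.51 relative to all genes, sebaceous gland genes from -1.87 to -1.03, Th2 genes from -1.05 to -0.65 and complement from -0.47 to -0.31, and all 4 stayed called. Of the lists' members, 10 cytokine genes and 1 neutrophil gene passed when adjusted over the list alone, against 0 over all genes.

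**Figure D2:**
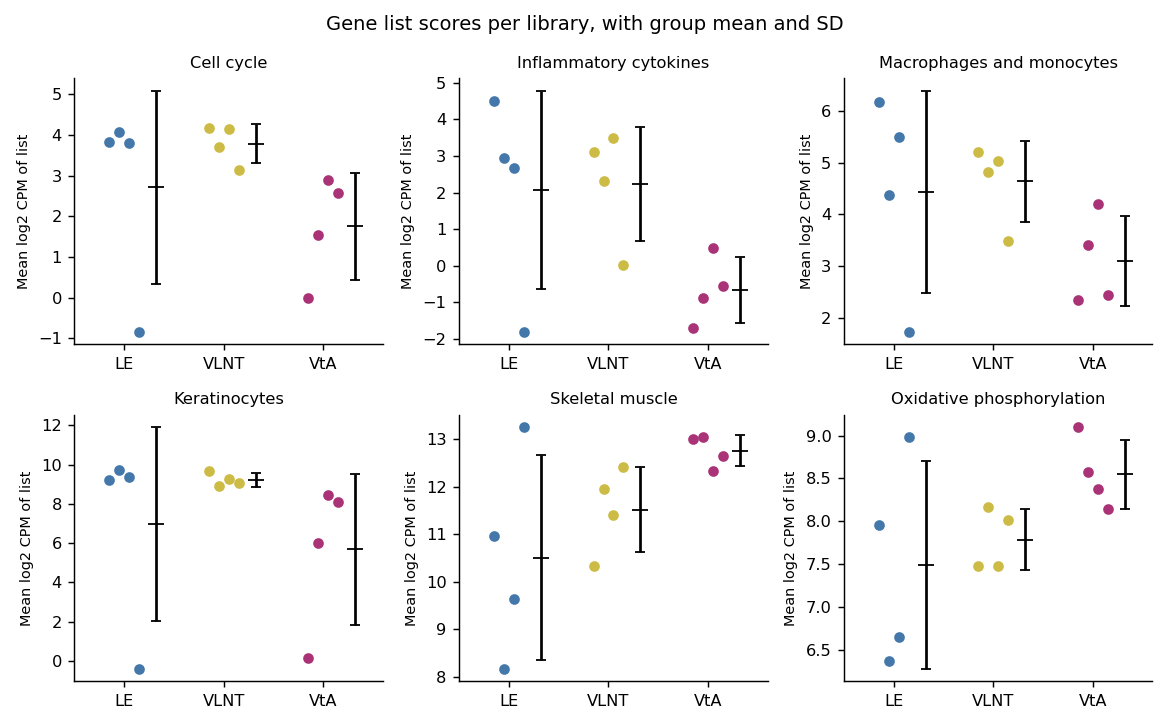
Mean log2 CPM of the genes of 6 fixed lists (y axis) per library in the 3 groups (x axis), with group mean and SD (n = 4) as bars. The 4 VtA libraries lie below the 4 VLNT libraries for cell cycle and keratinocyte genes, and LE4 lies below LE1 to LE3 for both.

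Across all genes, edgeR called 0 of 19740 in VtA against VLNT, with 1118 at an unadjusted p under 0.05 (60 higher, 1058 lower) where evenly spread p-values give 987. With these 8 libraries grouped 4 and 4 in every other way, the median was 102.5 such genes (highest 1626). DESeq2 called 152 (151 of them lower) and limma-voom with sample weights 3606, of which 1629 were higher and 1977 lower. The 5 genes with the smallest p were Tcf23, a basic helix-loop-helix factor (chromosome 5, 30968602 to 30988062), at 0.0767 ± 0.0255 CPM in VtA and 2.75 ± 1.13 in VLNT (-5.11 ± 0.78 SE, n = 4, adjusted p = 0.595), and 4 genes with adjusted p = 0.653 by edgeR. Of these, Degs2, a sphingolipid hydroxylase, was at 0.205 ± 0.196 and 15.6 ± 5.54 CPM (-6.21 ± 1.29), and Tmprss11b, an epithelial protease, at 0.0139 ± 0.0278 and 5.22 ± 2.65 CPM. Has3 was at 4.89 ± 1.38 and 23.1 ± 15.1 CPM (-2.24 ± 0.47), and Pla2g4d, a phospholipase, at 0.0104 ± 0.0209 and 3.76 ± 2.75 CPM. Tcf23 was called (adjusted p = 0.0282) when only VtA and VLNT entered the fit. Without LE4, which shares the estimate of the spread, 10 genes were called, all lower in VtA. These were Tcf23, Rptn, Tmprss11b, Chil1, Tubb3, Gm33497, Tmprss11d, Degs2, Ttpa and Pla2g4d (adjusted p = 0.00490 to 0.0467, edgeR), of which those outside the naming rule were named after their values were seen. With epidermis content as a covariate 7 lists remained of 26 (macrophages, cytokines, fibrosis, proteases, cell cycle, muscle regeneration and tendon), and with muscle content 8.

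The comparison of VtA with LE addressed the combined treatment. On average, inflammatory, T cell, interferon and macrophage genes were lower in VtA, and muscle and respiratory chain genes higher. LE4 went the other way. It scored below every VtA library for T cells (-2.96 against -2.73 to 0.19) and macrophages (1.72 against 2.34 to 4.19). The same held for cytokines (-1.81 against -1.70 to 0.48) and interferon response (1.49 against 1.83 to 2.91). For muscle LE4 lay above them (13.3 against 12.3 to 13.1). Inflammatory cytokines were lower in 20 of 22 genes (median -2.97, adjusted p = 5.86e-06 by camera), and T cell genes in 24 of 25 (median -2.50, adjusted p = 0.000140). Macrophage and monocyte genes were lower in 22 of 23 (median -1.66, adjusted p = 0.000271) and interferon response genes in 27 of 28 (median -0.85, adjusted p = 0.000285). Skeletal muscle genes were higher in 25 of 26 (median 1.15, adjusted p = 1.53e-06) and nuclear oxidative phosphorylation genes in 25 of 28 (median 0.75, adjusted p = 2.12e-05). These 6 calls were lost with an estimated correlation (adjusted p = 0.788 with an estimated correlation), and muscle reads were 24.3% ± 2.69 in VtA against 12.1% ± 11.8 in LE.

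Il1b, the interleukin-1β gene, was at 0.623 ± 0.634 CPM in VtA and 211 ± 329 in LE (702 in LE1 and 0.317 in LE4; log2 fold change -8.38 ± 2.05 SE, n = 4). Cxcl5 was at 0 counts in each VtA library and in LE4, and at 18.6 ± 20.6 CPM in LE. The T cell receptor gene Trac was at 0.374 ± 0.219 and 4.12 ± 3.803 CPM (-3.44 ± 0.97). Ccr7, a homing receptor, was at 0.273 ± 0.293 and 4.60 ± 7.17 (-4.04 ± 1.23). Cd14 was at 2.80 ± 1.13 and 87.4 ± 146 CPM (-4.96 ± 1.498). The scavenger receptor gene Msr1 was at 2.21 ± 1.55 and 16.7 ± 15.3 (-2.92 ± 0.89). Isg15, an interferon-induced ubiquitin-like protein, was at 2.103 ± 0.757 and 18.4 ± 22.6 CPM (-3.13 ± 1.03). Bst2 was at 9.97 ± 2.70 and 55.5 ± 78.5 (-2.48 ± 0.83). Ryr1, the muscle calcium release channel, was at 4350 ± 2145 CPM in VtA and 1207 ± 1824 in LE (1.85 ± 1.08). Neb, the nebulin gene, was at 5747 ± 2219 and 1546 ± 2440 (1.89 ± 1.13). Sdha, a subunit of succinate dehydrogenase, was at 858 ± 242 and 352 ± 414 CPM (1.29 ± 0.68). Uqcrc2 was at 439 ± 138 and 201 ± 208 (1.12 ± 0.60). Adjusted p was 0.288 to 0.351 for these genes by edgeR.

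Of the other lists called in VtA against LE, fibrosis and matrix genes (24 of 28 lower, median -1.49, adjusted p = 0.00129), hair follicle genes (19 of 19, median -6.66, adjusted p = 0.00129) and neutrophils (12 of 16, median -2.60, adjusted p = 0.00216) fell. Proteases (17 of 19, median -2.30, adjusted p = 0.00342), lymph node stroma chemokines (10 of 11, median -1.53, adjusted p = 0.00457) and cell cycle genes (25 of 27, median -1.75, adjusted p = 0.00496) were also lower. Dendritic cells (16 of 17, adjusted p = 0.0106), mast cells (12 of 13, adjusted p = 0.0186) and Th1 genes (12 of 14, adjusted p = 0.0189) fell as well. Mitochondrially encoded genes (13 of 13 higher, median 1.24, adjusted p = 0.000820), tendon genes (9 of 10, adjusted p = 0.00455), slow muscle fibres (8 of 11, adjusted p = 0.0144) and endothelial targets of Foxo1 (13 of 17, median 0.61, adjusted p = 0.0202) rose. None passed with an estimated correlation (adjusted p = 0.788 with an estimated correlation, but 0.851 for the cell cycle), and with muscle content as a covariate 0 of the 19 lists kept their call. Of these lists, skeletal muscle is its own covariate and could not keep it. The muscle scores of LE1 to LE3 (8.17 to 10.96) lay below those of VtA (12.3 to 13.1). The covariate fit therefore leans on LE4 (13.3), and the lost calls do not show that muscle accounts for the lists. In that fit oxidative phosphorylation genes turned to -0.39 relative to all genes, cell cycle genes to 0.86, Th1 genes to 0.61, mast cells to 0.15 and hair follicle genes to 1.92. With each single library left out, 12 of the 19 lists kept their call. Neutrophils, Th1 genes, dendritic cells, mast cells, slow fibres, hair follicle and cell cycle genes lost it in at least 1 fit: 4 of these without LE2, 4 without LE3, 3 without LE1, 3 without VtA1 and 1 without VtA4. Without LE1, which had 0.433% mitochondrial reads, the mitochondrial difference fell from 2.54 to 1.27 relative to all genes (adjusted p = 0.0126), that of macrophages from -1.31 to -0.73, of proteases from -1.68 to -1.10 and of the cell cycle from -0.93 to -0.55. Without LE2 skeletal muscle genes moved from 2.29 to 1.45 and oxidative phosphorylation genes from 1.09 to 0.66, without LE3 the latter to 0.72 and fibrosis genes from -1.04 to -0.67, and all of these stayed called. Over the list alone, 12 cytokine, 8 protease, 6 macrophage, 3 neutrophil and 1 mast cell genes passed, against 0 over all genes.

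Across all genes, edgeR called 0 of 19740 in VtA against LE, with 3256 at an unadjusted p under 0.05 (600 higher, 2656 lower) where evenly spread p-values give 987. With these 8 libraries grouped 4 and 4 in every other way, the median was 810 such genes (highest 9285). DESeq2 called 797 (22 higher, 775 lower) and limma-voom with sample weights 10639 (5518 higher, 5121 lower). The smallest p belonged to Tcf23 (0.0767 ± 0.0255 CPM in VtA, 1.59 ± 0.981 in LE, -4.32 ± 0.76 SE, n = 4) and Degs2 (0.205 ± 0.196 and 18.5 ± 17.5 CPM, -6.46 ± 1.31). Next were Csta3, a stefin (0.00696 ± 0.0139 and 32.8 ± 47.8 CPM), Tmprss11b (0.0139 ± 0.0278 and 5.70 ± 4.96 CPM) and Chil1, a chitinase-like protein (0.677 ± 0.463 and 64.8 ± 47.1 CPM, -6.56 ± 1.36), each with adjusted p = 0.288 by edgeR.

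This count depended on LE4: without it edgeR called 6288 genes, 2911 higher and 3377 lower in VtA, and without any other single library 0. LE1 to LE3 held 3.52% to 4.85% keratinocyte and 1.94% to 12.1% muscle reads, and VtA held 0.00449% to 1.24% and 21.9% to 28.1%. Of the 20431 genes tested in the fit without LE4, 3377 were called lower and 2911 higher. Those called lower included 17 of 27 cell cycle, 16 of 22 cytokine, 16 of 23 macrophage, 17 of 25 T cell and 14 of 28 interferon genes. In turn, 14 of 26 skeletal muscle, 16 of 28 oxidative phosphorylation, 7 of 17 Foxo1 target and 7 of 25 blood endothelial genes were called higher (2 of the latter were called lower). Il1b fell by 8.80 ± 1.61 on the log2 scale (SE, adjusted p = 0.00727, edgeR), Cd14 by 5.38 ± 1.25 (adjusted p = 0.0133) and Trac by 3.86 ± 0.73 (adjusted p = 0.00768). Isg15 fell by 3.54 ± 0.85 (adjusted p = 0.0145) and Tcf23 by 4.73 ± 0.47 (adjusted p = 0.00607). Sdha rose by 2.53 ± 0.42 (adjusted p = 0.00607), Uqcrc2 by 2.12 ± 0.40 (adjusted p = 0.00760) and Neb by 4.07 ± 0.92 (adjusted p = 0.0123).

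**Figure D3:**
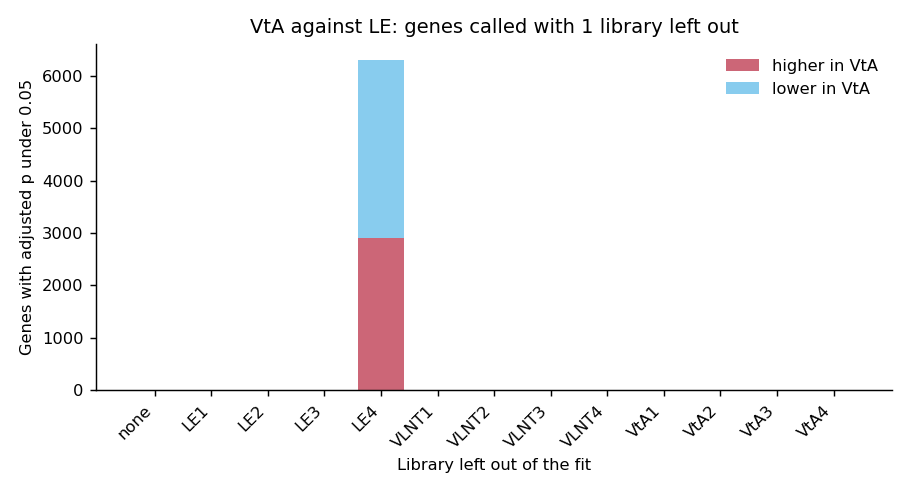
Genes with an adjusted p under 0.05 in VtA against LE (y axis) in the fit of all 12 libraries (none) and with each library left out (x axis), stacked by direction. Without LE4, 2911 genes were higher and 3377 lower in VtA, and every other fit called 0.

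The angiopoietin pathway was examined in all comparisons because the antibody acts on it. Tek, which encodes Tie2 (chromosome 4, 94739086 to 94874976), was at 18.4 ± 11.4 CPM in LE, 26.2 ± 7.08 in VLNT and 36.9 ± 5.75 in VtA (SD, n = 4). Each VtA library (31.9 to 44.1 CPM) lay above each VLNT library (15.8 to 31.6) and LE library (6.33 to 30.5), but the change passed against neither group. The log2 fold change was 0.49 ± 0.43 SE against VLNT (adjusted p = 0.654, edgeR) and 1.00 ± 0.44 against LE (adjusted p = 0.295). Without LE4, Tek passed against LE (1.32 ± 0.43, adjusted p = 0.0396), as did Ptprb, the vascular phosphatase that acts on Tie2 (2.08 ± 0.55, adjusted p = 0.0199), and Cdh5, which encodes VE-cadherin (1.73 ± 0.55, adjusted p = 0.0366). Pdpn, the podoplanin gene of lymphatic endothelium and of keratinocytes, fell in that fit (-2.06 ± 0.54, adjusted p = 0.0193). LE1, which stayed in that fit, held 6.33 CPM of Tek, against 11.5 in LE2 and 25.3 in LE3. It held 63.7 CPM of Pdpn, against 4.77 to 30.0 in the other LE libraries. Long transcripts were lower in LE1 than in LE2 and LE3, as given below, and transcript length was not taken into account for these genes. The libraries of that fit also parted in muscle reads, from 1.94% to 12.1% in LE1 to LE3 and from 21.9% to 28.1% in VtA, and in keratinocyte reads, from 3.52% to 4.85% in LE1 to LE3 and from 0.00449% to 1.24% in VtA. In the fit of all libraries Ptprb was at 31.3 ± 26.5, 47.0 ± 21.3 and 82.3 ± 29.6 CPM in LE, VLNT and VtA, Cdh5 at 46.1 ± 34.8, 69.4 ± 23.98 and 106 ± 34.9, and Pdpn at 29.9 ± 24.8, 25.1 ± 11.6 and 9.28 ± 5.18. Adjusted p for these 3 genes was 0.288 to 0.310 in VtA against LE and 0.653 to 0.660 in VtA against VLNT.

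Angpt2 (chromosome 8, 18690263 to 18741562), the ligand bound by the antibody, was at 6.93 ± 3.38, 8.16 ± 5.02 and 4.30 ± 0.951 CPM in LE, VLNT and VtA (VtA against VLNT -0.92 ± 0.47 SE, n = 4, adjusted p = 0.653, edgeR). Angpt1, the activating ligand of Tie2, was at 6.29 ± 2.89, 8.32 ± 3.29 and 12.9999 ± 5.92 CPM (VtA against LE 1.05 ± 0.43, adjusted p = 0.291). Tie1, the related orphan receptor, was at 26.7 ± 10.5, 28.3 ± 8.33 and 37.2 ± 8.62 CPM. Foxo1, a transcription factor restrained by Tie2 signalling, was at 21.8 ± 8.33, 24.97 ± 3.37 and 24.1 ± 4.18. Of lymphatic genes, Prox1 was at 2.98 ± 2.15, 4.33 ± 0.970 and 3.43 ± 0.840 CPM, and Flt4 at 8.21 ± 4.09, 11.4 ± 1.37 and 10.1 ± 3.15. Lyve1 was at 7.86 ± 5.40, 11.7 ± 5.86 and 8.26 ± 1.62, and Vegfc at 2.45 ± 0.333, 2.77 ± 1.08 and 2.603 ± 0.418. None of these genes passed in any of the 3 comparisons, and in VLNT against LE all 12 core genes had adjusted p = 0.99992 by edgeR. The sign of Tie1 in VLNT against LE and of Vegfc and Lyve1 in VtA against LE turned with RLE or upper-quartile factors and with DESeq2.

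As groups, the Tie2 pathway genes were not called in VLNT against LE (13 of 17 higher, adjusted p = 0.189), VtA against VLNT (7 of 17 higher, adjusted p = 0.890) or VtA against LE (9 of 17 higher, median 0.14, mean -0.04, adjusted p = 0.600). Lymphatic endothelial genes were higher in 14 of 20 in VLNT against LE (adjusted p = 0.346), lower in 16 of 20 in VtA against VLNT (adjusted p = 0.501) and evenly placed in VtA against LE (10 of 20 higher, adjusted p = 0.958). Endothelial junction genes had adjusted p = 0.894, 0.706 and 0.812 in the 3 comparisons, and lymphangiogenic factors 0.972, 0.687 and 0.788. Camera leaned up for lymphangiogenic factors in all 3 although their mean log2 fold changes were -0.09, -0.12 and -0.22, and for lymphatic endothelium in VtA against LE at a mean of -0.37 (median 0.01). Blood endothelial genes, called in VtA against VLNT, missed in VtA against LE (16 of 25 higher, adjusted p = 0.0644) and in VLNT against LE (adjusted p = 0.788).

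**Figure D4:**
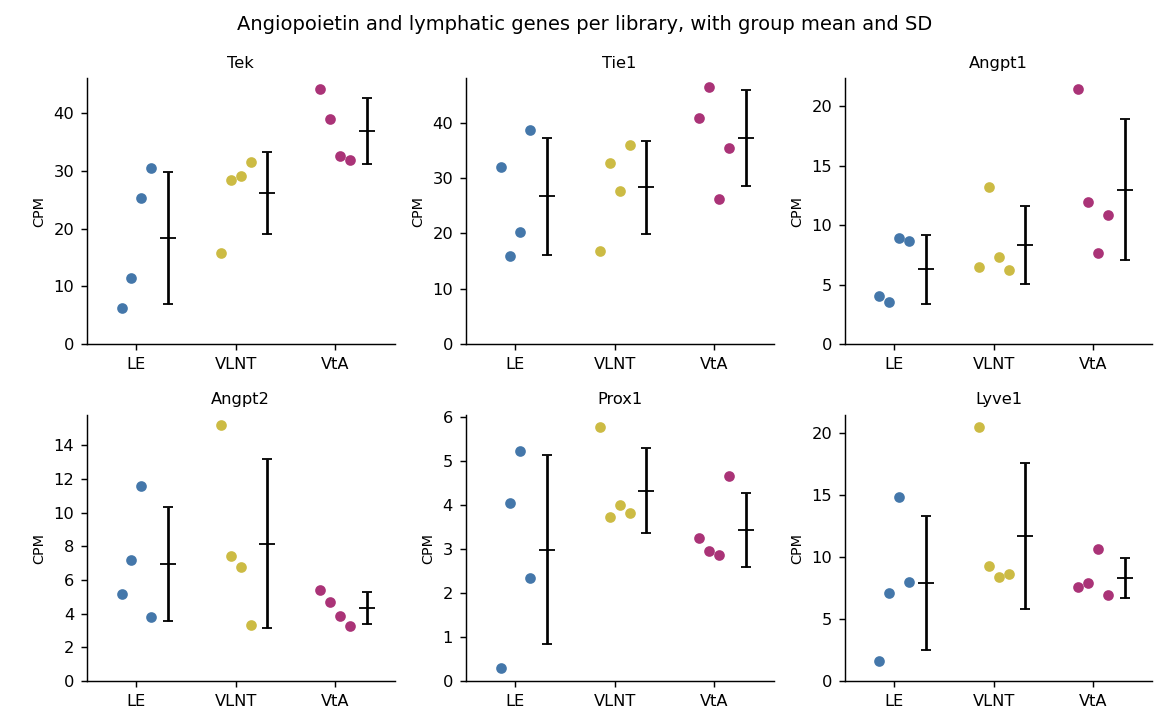
CPM (y axis, from 0) of Tek, Tie1, Angpt1, Angpt2, Prox1 and Lyve1 per library in LE, VLNT and VtA (x axis), with group mean and SD (n = 4) as bars. With TMM scaling, on which this order depends, Tek lies at 31.9 to 44.1 CPM in VtA, above every VLNT and LE library.

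The lists not named so far were not called in any comparison. They were adipocytes (adjusted p = 0.233 in VLNT against LE, 0.812 in VtA against VLNT and 0.683 in VtA against LE), thermogenic adipocytes (0.199, 0.381 and 0.162), and fibroblasts (0.976, 0.191 and 0.344). In the same order of comparisons, adjusted p was 0.809, 0.0903 and 0.234 for TGF-β signalling, 0.784, 0.244 and 0.314 for muscle atrophy, and 0.641, 0.557 and 0.822 for mural smooth muscle. For nerve and Schwann cells it was 0.809, 0.346 and 0.346, for erythrocytes 0.161, 0.0616 and 0.600, and for cartilage and bone 0.890, 0.142 and 0.222. Hypoxia genes (0.958, 0.670 and 0.777) and B cells (0.709, 0.809 and 0.976) were not called either, and camera leaned up for B cells in VtA against VLNT at a median of -0.31. By the exact permutation test of list scores, 1 list in VLNT against LE (thermogenic adipocytes), 2 in VtA against VLNT (cell cycle and keratinocytes) and 0 in VtA against LE had the smallest possible p of 0.0286, with an adjusted p of 0.48 over the 126 tests. Fry called 0 lists in each comparison (smallest adjusted p = 0.573, 0.573 and 0.362 for a shift one way, and 0.635, 0.580 and 0.580 for change in either direction).

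The comparisons of VLNT and VtA with LE share the LE libraries, so their fold changes were set against simulated groups with no change. The correlation of log2 fold changes across 19740 genes, which are not independent replicates, was 0.588, against a mean of 0.497 in 20 simulated sets (0.477 to 0.522), in which 18979 to 19072 genes passed the filter. The covariance was 0.651 against 0.333 (0.317 to 0.352). Of all genes 71.3% had the same sign, against 66.8% in the simulated sets. The simulated sets drew each gene on its own, with the same dispersion in all groups. They therefore lack the wide spread shared by many genes within LE (keratinocyte score SD 4.93 in LE, 0.35 in VLNT), which enters both comparisons. The values above the simulated range thus do not show a change shared by VLNT and VtA. With the LE libraries split 2 and 2, the correlation averaged -0.00324 over 6 assignments (-0.35 to 0.36) and the covariance -0.0909. At an unadjusted p under 0.05 in both, 14 genes were higher (0.821 for independent lists, 135 in the simulated sets) and 273 lower (49.6 and 64.1). EdgeR called 0 genes in both comparisons, DESeq2 1 (Gm9247) and limma-voom with sample weights 1355.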

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

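The tests of this part were chosen after the results were seen, except the counts over other splits of the 8 libraries of a comparison. The prediction for transcript length in LE1 was written before its value was seen, but after LE1 was seen to stand apart. A value stands here when 1 of the 4 libraries of a group lay far from the other 3, by Dixon's 95% critical value, which was passed by 20 of 135 groups of values, where chance gives about 6.75. LE4 held 9 of the 20 values.

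In LE4 the 10 most abundant genes took 30.5% of the reads, against 8.63% to 12.3% in LE1 to LE3. List scores of LE4, as mean log2 CPM, were -0.41 for keratinocytes (9.23 to 9.74 in the others), -0.089 for sebaceous gland (4.74 to 5.58), -0.84 for the cell cycle (3.81 to 4.07), -2.96 for T cells (1.45 to 1.91), -0.97 for Th2 genes (2.25 to 2.52), -3.54 for Th1 genes (0.65 to 1.13), -0.57 for mast cells (2.42 to 2.97) and 2.73 for immediate early genes (5.02 to 5.43).

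VLNT1 held 56.8 M counts, against 70.4 to 71.5 M in the other VLNT libraries, and VtA1 held 56.3 M, against 70.3 to 72.5 M. LE1, with 56.04 M, was the lowest of LE too (59.1, 68.6 and 70.1 M in LE2 to LE4), so the libraries numbered 1 were the shallowest of each group. In VLNT1 the interferon response score was 3.81 (2.64 to 2.76 in the others), the score of endothelial Foxo1 targets 4.18 (4.73 to 4.82) and that of plasma cells 3.97 (0.94 to 1.30). VLNT1 also held 5.77 CPM of Prox1 (3.72 to 4.0003) and 20.5 CPM of Lyve1 (8.36 to 9.28). The protease score was 3.73 in VLNT4 (5.33 to 5.66) and the tendon score 3.64 in VLNT2 (3.19 to 3.23). Angpt1 was at 13.2 CPM in VLNT2 (6.24 to 7.37), and Pdpn at 17.0 CPM in VtA3 (5.94 to 7.51).

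The lower immune, cell cycle and skin lists and the higher muscle lists of VtA against VLNT form the first pattern weighed. Less skin in the VtA pieces is a candidate explanation for part of it. With epidermis content as a covariate, 7 of the 23 called lists other than skin lists kept their call and direction. The keratinocyte scores used as the covariate did not overlap between VtA (0.16 to 8.46) and VLNT (8.88 to 9.68). The fit therefore cannot part skin from treatment, and the lost calls do not show that skin accounts for the lists. The cell cycle list moved from -1.73 to -0.38 relative to all genes with both covariates and was still called (adjusted p = 2.02e-09 by camera), so content and treatment cannot be told apart for it. ABTAA itself cannot be told apart from tissue content, since the highest keratinocyte share among VtA libraries, 1.24%, lay under the lowest of VLNT, 1.70%, and the groups do not overlap. Of the 35 splits of these 8 libraries, 4 gave at least 26 called lists (highest other 29), so chance could not be excluded for the lists. All 35 reach the 0 genes called by edgeR (highest other 0), which a count of 0 fixes, so the splits say nothing about genes called. At an unadjusted p under 0.05 by edgeR, 2 of 35 splits, the real one among them, gave at least 1118 genes. The median of the other splits was 102.5 and the highest 1626. This count was not among those fixed beforehand, and chance could not be excluded by it.

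The rise from 0 to 6288 genes in VtA against LE when LE4 was left out forms the second pattern. VtA1, VtA2 and VtA4 each correlated more with every other VtA library than with any of LE1 to LE3, by at least 0.0429. This cannot exclude a swap of LE4 with any of them. LE4, if labelled rightly, is an LE library that also correlated more with VtA (0.922) than with LE1 to LE3 (0.695). For VtA3 the correlations do not decide: it correlated more with the other VtA libraries on average, by 0.0710, but less with VtA1 (0.880) than with LE3 (0.901), and the labels as swapped gave 5780 genes in VtA against LE, against 0 as labelled. The keratins named below had a log2 ratio of -4.78 in VtA3, next to -5.70 in VtA2 and -5.11 in VtA4. It differed from the lowest of LE1 to LE3 by -4.19. VtA3 also held 0 counts of Cxcl5, against 1077 to 2418 in LE1 to LE3. The keratins and Cxcl5 were picked from these data with VtA3 counted as VtA, so they cannot test its label. A swap of LE4 with VtA3 therefore stays open. A swap with VLNT1 stays open, since VLNT1 correlated at 0.925 with the other VLNT libraries and at 0.930 with LE1 to LE3, a difference of -0.00504. A piece without skin in LE4 may account for its place: its keratinocyte share was 0.000793 times the lowest of LE1 to LE3. A wrong label without a partner stays open as well, since LE4 correlated with VtA more than with LE1 to LE3 by 0.227 (0.922 against 0.695), and no biological explanation of LE4 was tested. Without LE4, 1 of 35 splits, the real one, gave 6288 genes (highest other 0). These splits were chosen after the count of 6288 was seen and LE4 was singled out because of it, so chance is not excluded by them.

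With all libraries of VtA and LE, 11 of 35 splits gave at least 19 lists (highest other 26), so chance could not be excluded for the lists. The count of 0 genes is reached by all 35 splits whatever the data, here and in VLNT against LE, and decides nothing. At an unadjusted p under 0.05 by edgeR, 6 of 35 splits gave at least 3256 genes in VtA against LE (median of the others 810). In VLNT against LE, 29 of 35 gave at least 396 (median of the others 832.5). Chance could not be excluded by these counts, which were not fixed beforehand. The highest count of another split, 5780 genes, came from LE1 to LE3 with VtA3 against LE4 with the other VtA libraries, which points to a structure of the samples and is also the labelling that a swap of LE4 with VtA3 would give. In VLNT against LE, 34 of 35 splits gave at least 8 lists (highest other 25), so chance could not be excluded there either. The highest other count, 2421 genes, parted LE1 to LE3 with VLNT1 from the rest, again a structure of the samples and the labelling that a swap of LE4 with VLNT1 would give.

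The distance of LE1 from the other libraries forms the third pattern. A loss of long transcripts in LE1 may explain it in part: across 15024 genes, which are not independent replicates, transcript length and the log2 ratio of LE1 to LE2 and LE3 had a Spearman correlation of -0.485, against 0.0140 for LE2 to LE3. The median log2 ratio was 1.23 in the quartile of genes with the shortest transcripts and -0.96 in the quartile with the longest. Whether the LE1 piece held fewer mitochondria-rich cells could not be decided. Nuclear oxidative phosphorylation genes were higher in LE1 by 1.45 ± 1.09 (SD over 28 genes, 2 of them lower) while mitochondrially encoded genes were lower by 4.32. That rise is close to the 1.23 of the quartile with the shortest transcripts, and transcript length was not taken into account for these genes. No other biological explanation was tested for LE1.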

How the results depend on the processing

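The fits without LE4 and VtA1, without LE1, LE4 and VtA1, with both covariates and with library size alone were chosen after the data were seen, and the other alternatives were chosen before the data were examined. The cause was not tested for any change given here, except where fewer libraries or genes entered the fit.

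The count of 0 genes by edgeR held in all 3 comparisons with RLE and upper-quartile factors, TMM factors without tissue lists, both filters, the covariates, a 2-fold minimum, library size alone and limma on TPM. DESeq2 called 1 gene in VLNT against LE, 152 in VtA against VLNT and 797 in VtA against LE, with 1 shared by the comparisons against LE. Limma-voom with sample weights called 1362, 3606 and 10639 genes, with 1355 shared. A fit of only the 2 groups compared called 1 gene in VtA against VLNT, Tcf23. With single libraries left out, the count was 0 to 10 in VtA against VLNT and 0 to 6288 in VtA against LE, and only the fits without LE4 differed from 0. Without LE4 and VtA1, 1 gene (Tcf23) was called in VtA against VLNT and 4004 in VtA against LE (2120 higher, 1884 lower). Without LE1, LE4 and VtA1, 5466 genes were called in VtA against LE (3301 higher, 2165 lower). Most of the genes called were thus higher in these 2 fits, but lower without LE4 alone (2911 higher, 3377 lower).

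The number of lists called was 8 in VLNT against LE, 26 in VtA against VLNT and 19 in VtA against LE. Camera with an estimated correlation called 0, 0 and 0 lists, and fry called 0, 0 and 0. With single libraries left out, 5 (without VLNT2) to 17 (without LE4) lists were called in VLNT against LE, 20 to 28 in VtA against VLNT and 15 to 24 in VtA against LE. With skeletal muscle content as a covariate, the counts were 8, 8 and 5, and with epidermis content 13, 7 and 17. With both covariates they were 4, 5 and 4. Of these, 3, 8 and 0 (muscle), 5, 7 and 17 (epidermis) and 2, 5 and 4 (both) were called in the same direction without a covariate. With library size alone 6, 20 and 19 lists were called, 6, 16 and 16 of them in the direction of the TMM fit; 9 rose and 11 fell in VtA against VLNT (7 and 19 with TMM), and 9 rose and 10 fell in VtA against LE (6 and 13). Without LE4 and VtA1, 17 lists were called in VLNT against LE, and without LE1, LE4 and VtA1, 14. A list used as its own covariate is left out of the list values that follow. In the comparisons where a list was called, 298 of 1368 list values kept their direction but lost the call, 25 turned and 1045 kept both. Of 2514 values of named genes, 2299 kept direction and side of the threshold, 120 kept the direction and passed, and 95 turned.

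The labels do not say that the replicate numbers pair the samples, and the correlations do not show it. Deviations from the group means of libraries with the same number correlated at -0.43 to 0.56 across genes, which are not independent replicates, and 3 of 12 pairs exceeded 0.1. Between libraries of different groups and different numbers the range was -0.75 to 0.69, and 14 of 36 pairs exceeded 0.1. Only 2 libraries correlated best with a library of their own number. With the replicate number as a block, 5, 26 and 19 lists and 0, 0 and 0 genes were called by edgeR (184, 846 and 3263 at an unadjusted p under 0.05). The libraries numbered 1 were the shallowest of their groups (56.04, 56.8 and 56.3 M counts in LE, VLNT and VtA), so a shared sequencing run for them is not excluded; the block takes up such a difference.

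Scaling moved the median log2 fold change of all genes in VtA against LE from -0.11 to -0.20 (RLE and DESeq2), -0.22 (upper quartile) and -0.69 (library size alone). In VtA against VLNT it moved from -0.07 to -0.53 with library size alone, -0.30 with TPM + 1 and -0.50 with TPM + 0.1. In VLNT against LE the median of 0.01 became -0.14 with upper-quartile factors, 0.14 with TPM + 1 and 0.31 with TPM + 0.1.

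The values that turned are log2 fold changes for genes. For lists, the direction of the camera test turned, and the value given is the mean difference relative to all genes, which can keep its sign. With DESeq2, Tie1 turned to -0.025 in VLNT against LE, and Vegfc to -0.0058 and Lyve1 to -0.013 in VtA against LE. With RLE factors the same 3 values were -0.026, -0.0075 and -0.013, and with upper-quartile factors -0.089, -0.020 and -0.036, with Foxo1 at 2.9e-05 in VtA against VLNT. The stricter filter put Vegfc at -0.013 and Lyve1 at -0.013 in VtA against LE.

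With library size alone, Foxo1 turned to -0.035 in VLNT against LE and Tie1 to -0.064 in VtA against VLNT. In VtA against LE this setting put Foxo1 at -0.53, Prox1 at -0.56, Flt4 at -0.34, Vegfc at -0.44 and Lyve1 at -0.58. Limma on log2(TPM + 1) put Pdpn at 0.21, Lgals7 at 1.56, Sfn at 1.18, Tcap at 0.27 and Tnni2 at 0.21 in VLNT against LE, and Tie1 at -0.081 in VtA against VLNT. In VtA against LE it put Foxo1 at -0.15, Prox1 at -0.13, Flt4 at -0.044, Vegfc at -0.19 and Lyve1 at -0.084. With TPM + 0.1, Pdpn was at 0.27, Lgals7 at 1.87, Sfn at 1.34, Tcap at 0.27 and Tnni2 at 0.21 in VLNT against LE, Tie1 at -0.085 in VtA against VLNT, and Foxo1 at -0.13 and Vegfc at -0.23 in VtA against LE.

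Sample weights in limma-voom turned Angpt2 to -0.47, Prox1 to -0.16, Vegfc to -0.037, Lyve1 to -0.20, Sfn to 0.15, Tcap to 2.21 and Tnni2 to 1.68 in VLNT against LE. They put Foxo1 at 0.017, Flt4 at 0.055 and Vegfc at 0.068 in VtA against VLNT, and Prox1 at -0.34 and Lyve1 at -0.47 in VtA against LE.

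Skeletal muscle content as a covariate put Tie1 at -0.21 and Pdpn at 0.15 in VLNT against LE. In VtA against VLNT, Foxo1 was then at 0.11, Vegfc at 0.068, Tcap at -0.078, the interferon response list at 0.013 and the hair follicle list at 0.067. In VtA against LE, Tie1 was at -0.18, Angpt2 at 0.16, the Th1 list at 0.61, mast cells at 0.15, hair follicle at 1.92, the cell cycle at 0.86 and oxidative phosphorylation at -0.39. Epidermis content put Foxo1 at 0.11, Vegfc at 0.029, the Th1 list at 0.17, dendritic cells at 0.079, interferon response at 0.038 and mitochondrially encoded genes at -0.048 in VtA against VLNT. Both covariates put Tie1 at -0.27 in VLNT against LE. In VtA against VLNT they put Foxo1 at 0.13, Vegfc at 0.075, the Th1 list at 0.28, interferon response at 0.088 and the hair follicle list at -0.0082, where only the direction of the test turned. In VtA against LE, Tie1 was then at -0.21, Angpt2 at 0.40, the hair follicle list at 2.099 and mast cells at -0.055, where again only the direction of the test turned.

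Without LE4 and VtA1, the keratinocyte list turned to -0.30 and the cell cycle list to -0.20 in VLNT against LE, and Foxo1 to 0.035 in VtA against VLNT. Without LE1, LE4 and VtA1, Angpt2 was at -0.21, Foxo1 at -0.19, Prox1 at -0.13, Tcap at 2.55, Tnni2 at 1.97, the keratinocyte list at -0.33, sebaceous gland at -0.14 and the cell cycle at -0.16 in VLNT against LE. Foxo1 was at 0.035 in VtA against VLNT, and Foxo1 at -0.15, Prox1 at -0.46 and Lyve1 at -0.40 in VtA against LE.

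With single libraries left out, these values turned in at least 1 fit in VLNT against LE: Tie1 ranged from -0.12 to 0.30, Angpt2 from -0.25 to 0.59, Vegfc from -0.11 to 0.35, Pdpn from -0.61 to 0.43, Lgals7 from -1.98 to 0.36 and Sfn from -1.48 to 0.52. The skeletal muscle list ranged from -0.091 to 1.85 (below 0 without LE2), the keratinocyte list from -0.30 to 2.84 and the cell cycle list from -0.20 to 1.20 (both below 0 without LE4), and mitochondrially encoded genes from 0.021 to 2.44 with the direction of the test turned without LE1. In VtA against VLNT, Foxo1 ranged from -0.15 to 0.035 and Vegfc from -0.25 to 0.20. In VtA against LE, Foxo1 ranged from -0.012 to 0.37, Prox1 from -0.18 to 0.58, Flt4 from -0.0048 to 0.48, Vegfc from -0.028 to 0.13 and Lyve1 from -0.27 to 0.53.

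Depth limited the genes near 0 counts, such as Cxcl5. With list members at 0 in VtA set to 3 counts, the cytokine medians stayed at -2.55 and -2.97 and the hair follicle medians at -5.32 and -6.66 in VtA against VLNT and against LE. Only 2 cytokine genes and 1 hair follicle gene were at 0 in a group. So few genes at the low end of a list cannot move its median, so this says nothing about the effect of depth.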

Other observations

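The tests of this part were chosen after the values were seen. The keratins of stressed epidermis were compared with those of its basal layer as a ratio within each library, (Krt6a + Krt6b + Krt16) / (Krt5 + Krt14). The ratio was 1.92%, 3.63% and 2.90% in VtA2 to VtA4, 52.8% to 130% in VLNT and 66.2% to 106% in LE1 to LE3. LE4 and VtA1 were left out, since Krt5 and Krt14 together reached only 2.92 and 1.18 CPM, under a minimum of 100 CPM chosen after the values were seen; VtA1 would have given 42.6% from 0.504 CPM of the former, and LE4 had 0 CPM of them. As log2, the ratio was -5.20 ± 0.46 in VtA (SD, n = 3), -0.04 ± 0.60 in VLNT (n = 4) and -0.27 ± 0.34 in LE (n = 3). The exact permutation p was 0.0286 for VtA against VLNT, 0.1 for VtA against LE, the smallest possible there, and 0.6 for VLNT against LE (Benjamini-Hochberg 0.0857, 0.15 and 0.6). No p passed the adjustment. A lower amount of epidermis alone would leave the ratio unchanged. The mean log2 ratio of VtA differed from that of VLNT by -5.16, with no overlap among the libraries used. VtA3 was at 3.63% with a keratinocyte share of 1.24%, and VLNT4 at 52.8% with 1.70%. The genes, the ratio and the minimum of 100 CPM were picked after the values were seen. The difference therefore cannot decide against a lower amount of epidermis alone, and no other explanation was tested. Krt6a and Krt6b are near-identical copies, so their split is uncertain.

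The log2 ratio of Angpt2 to Tek was -3.11 ± 0.12 in VtA (SD, n = 4), -1.84 ± 1.33 in VLNT and -1.28 ± 1.20 in LE. The exact permutation p was 0.114 for VtA against VLNT and 0.0286 for VtA against LE (Benjamini-Hochberg 0.114 and 0.0571). VLNT4, at -3.26, lay within the range of the VtA libraries (-3.29 to -3.03) and LE4, at -3.01, next to it, so an effect of ABTAA on the ratio could not be told apart from the tissue content of the pieces.

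VLNT1 held 321 CPM of Igkc, against 0.418 to 2.18 CPM in the other VLNT libraries, and 32.6 CPM of Jchain, against 0.275 to 1.29 CPM. Both genes were chosen after their values were seen.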
